A study of Mus musculus with 19 samples.

How the data were processed

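RNA was measured in mouse hepatocytes of 3 populations. The animals carried an osteopontin-driven, tamoxifen-inducible Cre recombinase and the mT/mG reporter, in which Cre switches a cell and its descendants from red to green fluorescence. CTL samples were native hepatocytes of healthy liver, RED samples were native hepatocytes of chronically injured liver, and GREEN samples were hepatocytes of chronically injured liver that the labels describe as derived from the DR, an abbreviation they do not spell out. Each population had 5 biological samples. The 19 libraries were made in 2 experiments from 150 ng of total RNA, per the labels' protocols: 10 libraries of experiment 1 with a stranded poly(A) kit (TruSeq Stranded mRNA) and 9 libraries of experiment 2 with a kit that removes ribosomal RNA (KAPA HyperPrep RiboErase). CTL 5, RED 2, RED 3 and RED 4 had a separate library in each experiment. The method of RNA extraction is not given in the sources used here.

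The deposited tables held the authors' estimated counts per gene, which were not whole numbers and were not normalized. Per the submitters' processing notes, kallisto 0.43.1 and the genome build GRCm38 were used. The annotation release and the way transcripts were summed to genes are not given in the sources used here. Pseudo-alignment splits reads among near-identical sequences, so estimated counts of paralogs, processed pseudogenes and multigene families (the Mup genes, Cyp3a41a, Cyp2c69, Sult3a1, Rps2-ps13, Rps2-ps6, Rps26-ps1, Mup-ps13 and the histone genes among them) were treated as uncertain. The tables listed 35274 genes by Ensembl identifier. Symbols and GRCm38 positions came from a GENCODE annotation of the same build, in which 34845 of the identifiers (98.8%) were found without regard to version number. Total estimated counts per library were 22442600 to 34216800 in experiment 1 and 38061900 to 44177600 in experiment 2.

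Estimated counts were rounded to whole numbers. Each biological sample entered the tests with 1 library. For the 4 samples with a library in each experiment this was the experiment 2 library, so that each group had 2 libraries of experiment 1 and 3 of experiment 2. Genes were filtered with filterByExpr, which left 16387, and libraries were scaled by TMM. The 3 groups shared a model with group and experiment as terms, and RED versus CTL, GREEN versus RED and GREEN versus CTL were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Every adjusted p of a gene given without another tool's name is from this test. Standard errors are those of the fitted log2 fold change, and levels are CPM (counts scaled to a common library size with the TMM factors), with the standard deviation (SD) over 5 samples. The p-values measure the spread between samples that the labels call biological replicates; no label says which samples came from the same animal, and none gives the sex of the animals. The library codes in the descriptions give RED 2 and GREEN 1, RED 3 and GREEN 2, and RED 4 and GREEN 3 of experiment 2 the same code numbers. Deviations of these pairs from their group means correlated across genes at 0.53, 0.31 and 0.78, and the code numbers were taken to pair these samples. CTL and RED samples with the same title number, of healthy and of injured liver, had -0.11, -0.086, 0.42, 0.011 and 0.35. A correlation of 0.31 therefore does not by itself mark a shared animal. The tests had no term for the pairs, and fits with the pairs as a block are given beside the results they changed. In these fits the CTL libraries of experiment 2 were a block of their own unless CTL is said to be left out.

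For 35 gene lists fixed in advance the members past the threshold were counted, and camera (limma 3.58.1) was run with a preset correlation of 0.01 between genes and again with a correlation estimated per list. No list passed in any comparison with an estimated correlation. Lists with fewer than 5 tested members would not have been tested. The lists covered cell cycle and mitosis, DNA replication, DNA repair by homologous recombination and the Fanconi pathway, DNA repair by excision, mismatch repair and end joining, p53 targets and cell cycle arrest, senescence-associated secretion, biliary markers, mature hepatocyte markers, the pericentral zone, the periportal zone, cytochrome P450 and xenobiotic metabolism, bile acid synthesis and transport, cholesterol synthesis, fatty acid synthesis and lipid storage, fatty acid oxidation, the urea cycle and amino acid catabolism, the acute phase response, the interferon response, NRF2 and glutathione, the unfolded protein response, fetal and tumour-associated hepatocyte genes, YAP targets, extracellular matrix and stellate cell markers, Kupffer cell and macrophage markers, endothelial markers, lymphocyte markers, neutrophil markers, erythroid markers, immediate early and dissociation stress genes, oxidative phosphorylation, the circadian clock, male-biased liver genes, female-biased liver genes, replication-dependent histones, and TGF-beta, EMT and cytoskeleton genes. Of their symbols, 9 had no match.

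The named genes followed a rule. In each comparison they began with the 10 largest rises and 10 largest falls among genes past the threshold with a mean count of at least 50 in the higher group, an informative symbol and the same sign in each experiment fitted alone. Next came up to 4 members with the smallest adjusted p of each list that passed camera or had at least 3 members past the threshold. Last came Spp1, Krt19, Epcam, Sox9, Alb, Afp, Cdkn1a, Mki67, Ccnd1, Glul, Cyp2e1 and Cyp2f2. For the library kits they were the 10 largest rises and falls. Genes named outside this rule are marked as chosen after their values were seen. Samples, tests, lists, this rule and all alternatives but the last 7 were set before the data were examined.

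A fold against a group with no counts was computed against a floor of 3 counts over the whole group and is given as a lower bound. Against a group with 1 to 3 counts, the ratio is given with its 95% counting interval. Both cover counting error only, since reads of a library without molecular identifiers are not independent molecules. No 2 libraries of a group were the same library: their chi-square per degree of freedom was 84.5 at the lowest.

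The libraries of the 4 samples present in both experiments were compared with the sample as a term (14625 genes tested). Fold changes of the experiments were also correlated across genes. The alternatives tried were other scaling (DESeq2 size factors, library totals), DESeq2 1.42.0 and limma-voom, other filters on low counts (none, or at least 50 counts in at least 5 libraries), a 2-fold minimum, the other library of the repeated samples, all 19 libraries with the sample as a random block, no experiment term, each experiment alone, only the groups compared, blocks by the numbers in the titles or in the library codes, each library left out in turn, a term for sex, GREEN 4 and GREEN 5 left out, GREEN 3 left out as well, a block by the code numbers of experiment 2 with CTL kept, the same block with CTL left out, the same block in experiment 2 with CTL left out, and experiment 2 with CTL left out. The blocks by the numbers in the titles were fitted to only the groups compared, and the block by the library codes of both experiments left out CTL. The fits of each experiment alone used all of its libraries. These were 3 CTL, 5 RED and 2 GREEN in experiment 1 and 3 of each group in experiment 2. Samples with a library in each experiment therefore entered both fits. Python 3.11.15 with matplotlib 3.10.9 drew the plots.

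The tests were tried on simulated counts for the genes and libraries of each comparison, with 100 genes changed 2-fold and 100 changed 4-fold. In RED versus CTL edgeR recovered 27 of the 2-fold and 66 of the 4-fold changes, with 7 false calls among 100. In GREEN versus RED it recovered 38 and 69, with 4 false calls among 111, and in GREEN versus CTL 33 and 67, with 4 among 104. DESeq2 recovered 43 and 77, 55 and 80, and 53 and 85 in the same order, with 46 false calls among 166, 40 among 175 and 44 among 182. limma-voom recovered 26 of 100 and 61 of 97 in RED versus CTL, 39 of 99 and 65 of 97 in GREEN versus RED, and 31 of 100 and 65 of 98 in GREEN versus CTL. The test of a difference between the experiments recovered none of the 2-fold differences in any comparison, and 8, 23 and 0 of the 4-fold differences. The comparison of the library kits recovered 87 and 98, with 25 false calls among 210. Camera found the list whose members were changed in each of the 3 comparisons, with 1, 1 and 0 of the other lists also past the threshold in the same order. Genes were simulated independently of each other, whereas the estimated correlation of the endothelial list in RED versus CTL was 0.929. The trial therefore cannot show how often camera passes unchanged lists whose members vary together.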

Results

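The 15 samples gave 5 CTL, 5 RED and 5 GREEN libraries for the tests, 2 of each group from experiment 1 and 3 from experiment 2. Libraries of experiment 1 held counts above 0 for 16338 to 19909 genes and those of experiment 2 for 19459 to 21876. The TMM factors were highest in GREEN 4 (1.49), GREEN 5 (1.43) and GREEN 3 (1.35) and lowest in CTL 4 (0.624). Between groups the median log2 fold change of all genes was 0.05 for RED versus CTL, -0.02 for GREEN versus RED and 0.11 for GREEN versus CTL, and 0.33, 0.42 and 0.83 when libraries were scaled by their totals.

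**Figure D1:**
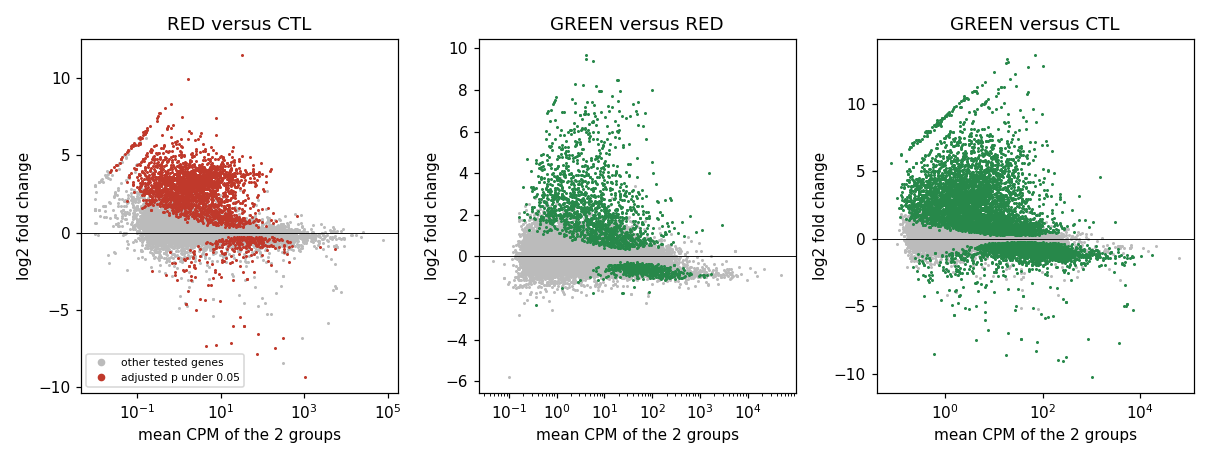
log2 fold change of each gene (vertical axis) against its mean level in CPM (horizontal axis, log scale) for RED versus CTL, GREEN versus RED and GREEN versus CTL. Coloured points had an adjusted p under 0.05 and grey points did not; scaled by library totals, the split of GREEN versus RED was 4289 higher and 40 lower.

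RED versus CTL asked how native hepatocytes of chronically injured liver differed from those of healthy liver. RED samples held more RNA of genes typical of matrix-producing stellate cells, endothelial cells and macrophages. The collagen gene Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) rose from 1.498 ± 0.769 to 37.9 ± 20.6 CPM (log2 fold change 4.64, standard error 0.45, 5 samples per group). Flt4 (ENSMUSG00000020357.3, chromosome 11, 49609263 to 49652739), which encodes a vascular endothelial growth factor receptor, rose from 9.02 ± 4.99 to 109.6 ± 48.3 CPM, and the macrophage scavenger receptor gene Marco (ENSMUSG00000026390.7, chromosome 1, 120474538 to 120505024) from 0.801 ± 0.513 to 37.4 ± 41.4 CPM. Cyp8b1 (ENSMUSG00000050445.4, chromosome 9, 121914356 to 121916305), which encodes the sterol 12-alpha-hydroxylase of bile acid synthesis, fell from 266.1 ± 88.0 to 59.0 ± 26.6 CPM (log2 -2.08, standard error 0.37). In all, 2652 genes passed the threshold, 2326 higher and 326 lower in RED. Of these, 2273 had a fitted change over 2-fold, 2160 of them higher, without a test against 2-fold. Within the experiments, 2093 genes passed in experiment 1 alone (3 CTL and 5 RED libraries) and 1207 in experiment 2 alone (3 CTL and 3 RED). All 2613 of the pooled calls that were tested in both had the same sign in each. CTL and RED samples with a library in each experiment entered both fits, so the fits are not independent. The calls were also picked in the pooled fit of the same samples, which favours equal signs, so this agreement is no replication.

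Most markers of endothelial, stellate and macrophage cells were higher in RED. Of 30 endothelial markers, 30 rose (30 adjusted over the list alone), with a median log2 fold change of 3.80. All 30 rose in experiment 1 alone and 29 in experiment 2 alone. Flt4 had 4.195 and 3.14 in the experiments, and Vwf rose by 3.35 and Ptprb by 3.99 in the pooled fit. Of 30 extracellular matrix and stellate cell markers, 29 rose (30 adjusted over the list alone, median 3.98, 27 and 24 in the experiments alone). Col3a1 rose by 4.91 (adjusted p = 2.1e-04) and Col1a2 by 4.79. The camera test of this list gave an adjusted p of 1.5e-34, and 0.20 with an estimated correlation. Of 30 Kupffer cell and macrophage markers, 26 rose (27 adjusted over the list alone, median 3.24), 26 in experiment 1 alone and 9 in experiment 2 alone. Lyz2 (ENSMUSG00000069516.8, chromosome 10, 117277331 to 117282321) had 112.3 ± 97.0 CPM in RED and 5.36 ± 3.25 in CTL. Of 13 neutrophil markers, 9 rose (10 adjusted over the list alone, median 4.15, and 4.37 with genes near 0 counts at their bound), but 2 in experiment 2 alone. S100a9 rose by 4.53. Lymphocyte markers had 5 of 17 higher and 1 lower (7 and 1 adjusted over the list alone, 7 and 0 by library totals), with Cd52 at 4.12, and erythroid markers had 1 of 12 higher (1 adjusted over the list alone).

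Most cell cycle genes and some arrest genes were higher in RED. Of 40 cell cycle and mitosis genes, 33 rose (35 higher and 1 lower adjusted over the list alone, median 2.94), 10 higher and 1 lower in experiment 1 alone and 4 higher in experiment 2 alone. With the experiment effect removed, their mean log2 CPM was 2.72 to 2.88 in RED 3, RED 4 and RED 5. It was 1.17 in RED 1, 0.34 in RED 2 and -1.41 to 0.58 in CTL. RED 1 and RED 2 were also the lowest RED samples for the endothelial, matrix and macrophage lists. Cdk1 (ENSMUSG00000019942.13, chromosome 10, 69335146 to 69352938) rose from 1.00 ± 0.261 to 8.40 ± 4.84 CPM, with log2 fold changes of 3.16 and 3.13 in the experiments. Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361) rose by 3.30 (adjusted p = 0.014), which limma-voom and either experiment alone did not reach. Of 30 DNA replication genes 2 rose (0 adjusted over the list alone, 5 by library totals), of 24 genes of homologous recombination and the Fanconi pathway 6 (7 adjusted over the list alone), and of 24 replication-dependent histones 3 (0 adjusted over the list alone). Of 28 genes of excision, mismatch repair and end joining 0 passed (0 adjusted over the list alone). Their median was -0.02 and their mean 0.0040, and the median 0.27 by library totals. Of 27 p53 targets and cell cycle arrest genes, 9 rose (12 adjusted over the list alone), 6 and 3 in the experiments alone, with Phlda3 at 3.75 (standard error 0.47) and Cdkn2a at least 26.6-fold above a CTL group with 0 counts. Cdkn1a had a log2 value of 2.77 and did not pass (adjusted p = 0.083), though it did with DESeq2, in experiment 1 alone and without CTL 1 or RED 2. Of 22 genes of senescence-associated secretion, 14 rose (16 higher and 1 lower adjusted over the list alone, median 2.98), 15 and 8 in the experiments alone. Il1a rose from 1.43 ± 0.617 to 25.7 ± 27.0 CPM and Ccl2 by 5.26.

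Genes of remodelling rose in part. Of 34 TGF-beta, EMT and cytoskeleton genes, 19 rose (22 adjusted over the list alone, median 1.68), 14 and 11 in the experiments alone, with Vim at 4.47 and Anxa1 at 4.87. Of 24 YAP targets 11 rose (15 adjusted over the list alone, median 1.66, and 1.26 with genes near 0 counts at their bound), among them Crim1 (1.91) and Tgfb2 (4.33). Of 23 fetal and tumour-associated hepatocyte genes 12 rose (12 adjusted over the list alone, median 2.65, and 1.78 at the bounds), among them Lpl, from 10.5 ± 5.89 to 141.2 ± 30.4 CPM, and Sox4 (4.04, standard error 0.49). Afp was at 0.11 and did not pass (adjusted p = 0.86). Of 30 biliary markers 7 rose (8 adjusted over the list alone, median 1.57, and 1.39 at the bounds), 8 and 3 in the experiments alone. Krt19 (ENSMUSG00000020911.14, chromosome 11, 100140810 to 100148665), a keratin of bile duct cells, held 81 counts in RED and 1 in CTL, a ratio of 72.6 (counting interval 12.7 to 2902), but its call ended under limma-voom and in experiment 2 alone. Spp1 (0.63), Epcam (1.71) and Sox9 (1.63) did not pass, though Epcam did without CTL 5, and Sox9 with DESeq2, in experiment 1 alone and without CTL 1. Of 29 immediate early and dissociation stress genes 6 rose (6 adjusted over the list alone), with Egr3 at a ratio of 31.4 (counting interval 10.4 to 154.5) over 3 counts in CTL.

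Few hepatocyte genes passed. Of 29 mature hepatocyte markers 1, Serpina1c, fell (0 adjusted over the list alone, median -0.38), a call that ended by library totals, in either experiment alone and without any of CTL 1, CTL 3, CTL 4, CTL 5, RED 2 to RED 5, GREEN 2, GREEN 3 and GREEN 5. Alb had a log2 value of -0.50 without passing. Of 28 pericentral genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, 3 and 0 by library totals), of 30 periportal genes 0 passed (0 adjusted over the list alone, median -0.28), and of 31 genes of cytochrome P450 and xenobiotic metabolism 3 fell (0 adjusted over the list alone, median -0.46). Glul (-0.63), Cyp2e1 (-0.68) and Cyp2f2 (-0.85) did not pass. Of 25 genes of bile acid synthesis and transport 4 fell (4 adjusted over the list alone), 2 and 3 in the experiments alone, where Cyp8b1 had -1.90 and -2.62. Of 24 cholesterol synthesis genes 1, Stard4, fell (1 adjusted over the list alone), though not by library totals or in experiment 2 alone. Of 25 genes of fatty acid synthesis and lipid storage 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of -0.11, a mean of 0.011, and a median of 0.17 by library totals. Cd36 rose by 3.00 and Fabp4 by 3.90, and Thrsp fell by 1.81, though these 3 calls ended in experiment 2 alone. Fabp4 was also a member of the endothelial list, of which 30 of 30 rose with a median of 3.80, so its rise need not be one of hepatocytes. Fatty acid oxidation had 0 of 27 past (0 adjusted over the list alone, median -0.0023, mean 0.097, median 0.25 by library totals), the urea cycle and amino acid catabolism 0 of 30 (0 adjusted over the list alone, median -0.25), the acute phase response 0 of 28 (0 adjusted over the list alone, median -0.22, and 0.13 by library totals) and oxidative phosphorylation 0 of 32 (0 adjusted over the list alone, median -0.19, and 0.07 by library totals).

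Stress lists gave mixed values. Interferon response genes had 3 of 30 higher (Ifit2 3.73) and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.07 where the camera test pointed down. NRF2 and glutathione genes had 3 of 28 higher (3 adjusted over the list alone, 6 by library totals), with Akr1b8 at 4.26 and Cbr3 at 4.25, of which the latter ended in experiment 2 alone, as did Ifit2. Unfolded protein response genes had 2 of 26 higher (1 adjusted over the list alone), with a median of -0.15, a mean of 0.052 and a median of 0.17 by library totals. Circadian clock genes had 2 of 20 lower (2 adjusted over the list alone), with Bhlhe41 at -2.30, a call that ended by library totals, under limma-voom, and without CTL 4, CTL 5, RED 3 or RED 4. Experiment 1 alone had 1 higher and 5 lower, and experiment 2 alone 0.

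Genes with known sex bias in liver were among the largest falls. Summed Y-linked genes were high in CTL 1, CTL 4 and CTL 5 but only in RED 4 and RED 5, so the groups were not balanced in them. Levels of the sex-biased lists split by these genes are given under the other observations. Of 22 male-biased genes 3 fell (3 adjusted over the list alone, median -1.67), and of 20 female-biased genes 3 (4 adjusted over the list alone, median -3.48). Mup19 (ENSMUSG00000078673.10, chromosome 4, 61778324 to 61782269) had 403.3 ± 297.5 CPM in CTL and 2.18 ± 2.45 in RED (log2 -7.50, standard error 1.31), but its reads are hard to separate from those of other Mup genes and its call ended in experiment 2 alone. The calls of the female-biased genes Cyp3a41a and Sult3a1 both ended without CTL 2, CTL 3, RED 2, RED 4 or RED 5. Among the largest rises were Tinag (ENSMUSG00000032357.12, chromosome 9, 76951693 to 77045794), at least 162-fold, and Sele (ENSMUSG00000026582.6, chromosome 1, 164048234 to 164057677), with a ratio of 305 (counting interval 54.3 to 12068). The processed pseudogene Rps2-ps13 had a ratio of 3339 (counting interval 1142 to 16195) over 3 counts in CTL, with 113.5 CPM in RED 5 and 0.343 in RED 1, and its call ended under limma-voom, in either experiment alone and without CTL 5.

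GREEN versus RED asked how the DR-derived hepatocytes differed from native hepatocytes likewise of chronically injured liver. GREEN samples held far more RNA of genes typical of bile duct cells. Krt19 rose from 0.488 ± 0.248 to 54.9 ± 41.0 CPM (log2 fold change 6.63, standard error 0.63, 5 samples per group), and Muc1 (ENSMUSG00000042784.9, chromosome 3, 89229057 to 89233381), which encodes an apical membrane mucin, from 0.397 ± 0.158 to 47.3 ± 32.99 CPM (log2 6.73, standard error 0.59). Epcam (ENSMUSG00000045394.8, chromosome 17, 87635979 to 87651129), which encodes an epithelial adhesion molecule of bile ducts and progenitor cells, rose from 0.445 ± 0.250 to 77.8 ± 58.7 CPM. F9 (ENSMUSG00000031138.4, chromosome X, 59999464 to 60030759), which encodes clotting factor IX, fell from 215 ± 80.1 to 96.1 ± 34.3 CPM (log2 -1.09, standard error 0.30). In all 2114 genes passed, 1586 higher and 528 lower in GREEN, and 1326 of them had a fitted change over 2-fold, 1293 of these higher. By library totals 4289 were higher and 40 lower. Experiment 1 alone, with all its libraries (5 RED and 2 GREEN), gave 3062 higher and 2289 lower. Experiment 2 alone (3 RED and 3 GREEN) gave 76 higher and 1 lower. All 2104 of the pooled calls that were tested in both had the same sign in each. RED samples with a library in each experiment entered both fits, so the fits are not independent. The calls were also picked in the pooled fit of the same samples, which favours equal signs, so this agreement is no replication. With the 3 RED and GREEN pairs of experiment 2 as a block, 1813 were higher and 967 lower. With CTL left out of the fit, 1283 genes passed without the block and 1305 with it. Experiment 2 without CTL gave 0 genes without the block (1336 at an unadjusted p under 0.05 in edgeR, 0 and 1252 in limma-voom) and 850 higher and 7 lower with it.

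The number of calls in GREEN versus RED hung on single libraries. It was 896 without RED 1, 1396 without RED 5, 866 without GREEN 3, 904 without GREEN 4, 912 without GREEN 5 and 3515 without GREEN 1. Without GREEN 4 and GREEN 5 it was 268, all higher, and without GREEN 3, GREEN 4 and GREEN 5 it was 52, of which 1 was lower. With the experiment effect removed, the mean log2 CPM of the biliary markers was 6.35 in GREEN 4, 5.65 in GREEN 5 and 6.19 in GREEN 3, and 3.84 in GREEN 1 and 4.45 in GREEN 2. That of the mature hepatocyte markers was 9.26, 9.88, 9.75, 10.65 and 10.51 in the same order.

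**Figure D2:**
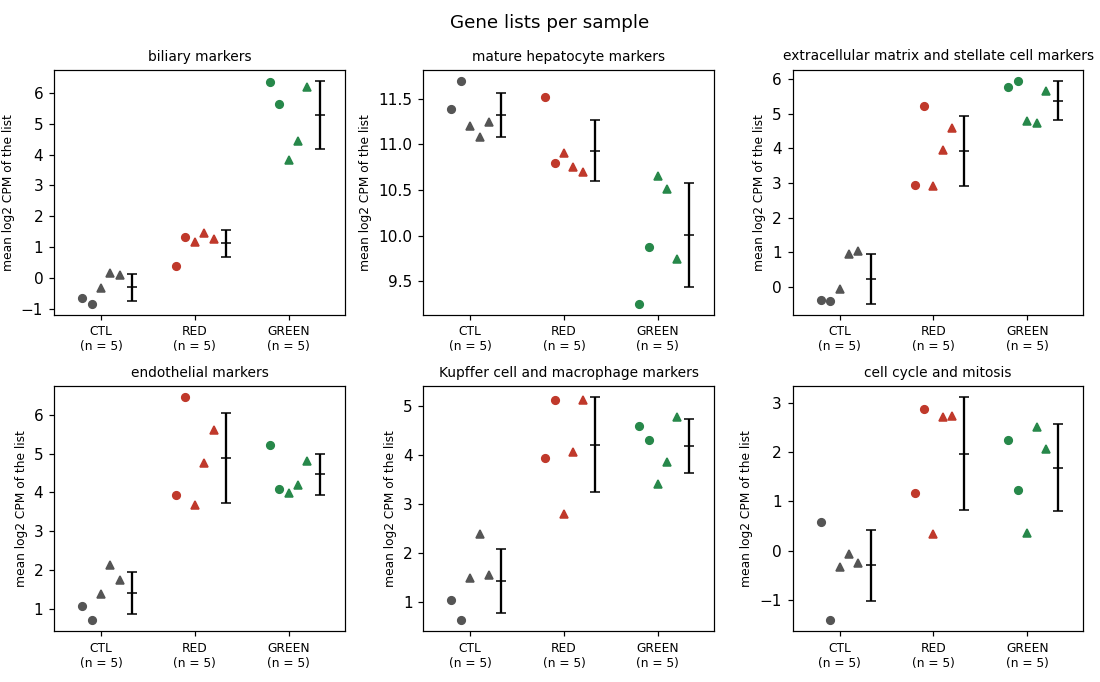
Mean log2 CPM of the members of 6 gene lists, with the experiment effect removed (vertical axis), in each sample of CTL, RED and GREEN. Circles mark experiment 1, triangles experiment 2, and bars the mean ± SD of 5 samples. Scaled by library totals, the median log2 fold change of the Kupffer cell and macrophage list in GREEN versus RED turned from -0.43 to 0.03.

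Of 30 biliary markers, 25 rose in GREEN over RED (29 adjusted over the list alone, median 4.68), 27 in experiment 1 alone, 5 in experiment 2 alone, 16 without GREEN 4 and GREEN 5 and 6 without GREEN 3 as well. The camera test gave an adjusted p of 2.8e-30, and 0.23 with an estimated correlation. With the pairs of experiment 2 as a block 26 rose, and 20 in experiment 2 without CTL. Cldn7 (7.17, adjusted p = 9.4e-05) and Muc1 lost their calls only in experiment 2 without CTL and without the block. The calls of Krt19 and Cldn4 (7.93) ended in experiment 2 alone, where Krt19 had 6.26 against 7.41 in experiment 1, but passed there with the block and without CTL. The call of Epcam, with 8.08 and 6.90 in the experiments, ended in experiment 2 alone without the block and without GREEN 3, GREEN 4 and GREEN 5. Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050), which encodes osteopontin, whose promoter drove the Cre, had 2868 ± 2874 CPM in GREEN and 154 ± 142.2 in RED (log2 3.99, standard error 1.22, adjusted p = 0.046). Its call ended with the block (GREEN versus RED Spp1 3.74, adjusted p = 0.055), in experiment 2 alone without the block, under limma-voom, and whenever CTL 1, CTL 4, GREEN 3, GREEN 4, GREEN 5 or any RED sample was left out. Sox9 (ENSMUSG00000000567.5, chromosome 11, 112782224 to 112787760) had 1.72 and did not pass (adjusted p = 0.078), though it did with the block (GREEN versus RED Sox9 1.65, adjusted p = 0.042), without CTL, with DESeq2, limma-voom and library totals, and without CTL 1, CTL 3 or GREEN 1. Among the largest rises were BC067074 (ENSMUSG00000021763.17, chromosome 13, 113293159 to 113379711), with a ratio of 1427 (counting interval 256 to 56393), Scara3 (ENSMUSG00000034463.4, chromosome 14, 65919394 to 65953935), from 0.698 ± 0.711 to 201.1 ± 163.9 CPM, and Ugt8a (7.97).

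**Figure D3:**
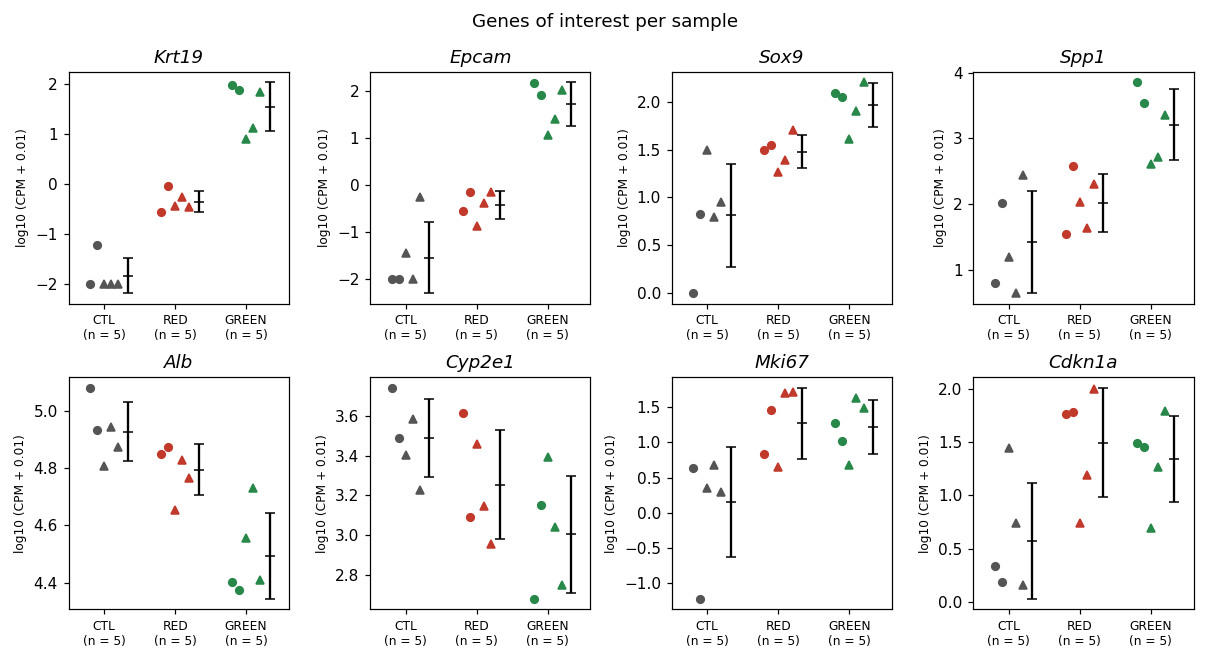
Level of 8 genes (vertical axis, log10 of CPM plus 0.01) in each sample of CTL, RED and GREEN; circles mark experiment 1, triangles experiment 2, and bars the mean ± SD of 5 samples. Scaled by library totals, the log2 fold change of Mki67 in GREEN versus RED turned from -0.35 to 0.05.

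Other lists with rises were smaller. Of 24 YAP targets 12 rose (15 adjusted over the list alone, median 1.31), 16 in experiment 1 alone, 1 in experiment 2 alone and 2 without GREEN 4 and GREEN 5. With the pairs of experiment 2 as a block 14 rose, and 11 in experiment 2 without CTL. Ankrd1 rose by 7.40 (standard error 0.61), a call that ended in experiment 2 without CTL and without the block. Ccn1 rose by 2.71, a call that ended in experiment 2 alone without the block and without GREEN 4 and GREEN 5. Of 30 extracellular matrix and stellate cell markers 11 rose (12 adjusted over the list alone, median 1.08), 12 and 1 in the experiments alone and 2 without GREEN 4 and GREEN 5. Col1a1 had 229.9 ± 76.1 CPM in GREEN and 37.9 ± 20.6 in RED (log2 3.05 and 2.54 in the experiments), its call ending in experiment 2 alone without the block and without the 3 GREEN libraries, while Mfap4 (4.70) lost its call where Ankrd1 did. With the block 13 of these markers rose, and 12 in experiment 2 without CTL. Of 29 immediate early and dissociation stress genes 9 rose (14 adjusted over the list alone, median 0.56), 13 in experiment 1 alone, 15 by library totals, 0 in experiment 2 alone and 0 without GREEN 4 and GREEN 5. Fosb (ENSMUSG00000003545.3, chromosome 7, 19302696 to 19310051) had 1007 ± 638.8 CPM in GREEN and 253.4 ± 100.1 in RED. Of 23 fetal and tumour-associated hepatocyte genes 7 rose (8 higher and 1 lower adjusted over the list alone, median 0.80), 10 higher and 1 lower in experiment 1 alone and 1 higher in experiment 2 alone. The list members Epcam, Cd24a, Prom1 and Tspan8, were also biliary markers. Of 34 TGF-beta, EMT and cytoskeleton genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, 11 and 0 by library totals), with S100a6 at 4.11, a call that ended under the alternatives that ended that of Ccn1. Senescence-associated secretion had 3 of 22 higher (3 adjusted over the list alone, 6 and 0 in the experiments alone, 5 by library totals), with Lif at 2.61, a call that also ended without RED 1, RED 3, RED 4, GREEN 3, GREEN 4 or GREEN 5.

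Few hepatocyte genes passed as lower in GREEN. Of 29 mature hepatocyte markers 3 fell (19 adjusted over the list alone, median -0.88), 25 in experiment 1 alone, 0 in experiment 2 alone, 1 by library totals and 0 without GREEN 4 and GREEN 5. F9 had -1.98 in experiment 1 and -0.55 in experiment 2. Apoc3 fell by 0.95 and Apoh by 0.90. Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602) had 34270 CPM in GREEN and 65490 in RED and did not pass (adjusted p = 0.31), though it did with DESeq2 and limma-voom. Of 25 genes of bile acid synthesis and transport 1 rose and 4 fell (1 and 14 adjusted over the list alone), 1 and 15 in experiment 1 alone 0 in experiment 2 alone, and 1 and 2 by library totals, with Cyp8b1 at -2.16 and -0.92. Of 31 genes of cytochrome P450 and xenobiotic metabolism 3 fell (3 adjusted over the list alone, median -0.82), of 30 periportal genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, median -0.86), and of 28 pericentral genes 1 rose (1 adjusted over the list alone, median -0.66). Cyp2f2 (-1.16) and Glul (-0.23, and 0.18 by library totals) did not pass. Of 32 oxidative phosphorylation genes 8 fell (32 adjusted over the list alone, median -0.53), 28 in experiment 1 alone, 0 in experiment 2 alone and 0 by library totals, with Cycs and Ndufa1 each at -0.64. Of the remaining metabolic lists, cholesterol synthesis had 2 of 24 lower (0 adjusted over the list alone), fatty acid synthesis and lipid storage 2 of 25 lower (0 adjusted over the list alone), fatty acid oxidation 1 of 27 lower (0 adjusted over the list alone), the urea cycle and amino acid catabolism 0 of 30 (0 adjusted over the list alone, 22 lower in experiment 1 alone) and the acute phase response 1 of 28 higher (1 adjusted over the list alone). By library totals 0 genes were lower in the periportal, cholesterol, fatty acid synthesis and fatty acid oxidation lists. The call of every one of these falls ended in experiment 2 alone, with or without the block, and without GREEN 4 and GREEN 5. With the pairs of experiment 2 as a block and CTL kept, 7 mature hepatocyte markers, 8 genes of cytochrome P450 and xenobiotic metabolism, 10 bile acid genes, 4 pericentral genes, 7 cholesterol synthesis genes, 4 genes of fatty acid synthesis, 2 of fatty acid oxidation and 6 of the urea cycle and amino acid catabolism were lower. Without CTL and without the block, 0 mature hepatocyte markers and 1 oxidative phosphorylation gene were lower, and F9, Apoc3, Apoh, Cyp8b1 and Ndufa1 did not pass. The call of F9 also ended without RED 1, RED 2, RED 5, GREEN 3, GREEN 4 or GREEN 5, and that of Cyp8b1 without GREEN 4 or GREEN 5.

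Markers of other liver cells gave few calls between GREEN and RED. Of 30 Kupffer cell and macrophage markers 5 fell (3 higher and 6 lower adjusted over the list alone), with a median of -0.43, but by library totals 4 rose, 0 fell and the median was 0.03. Marco was at -1.78 (adjusted p = 0.042) and Vsig4 at -1.75, and both calls ended in either experiment alone and without any of RED 1, RED 4, RED 5 or the GREEN samples. Of 30 endothelial markers 0 passed (0 adjusted over the list alone, median -0.83), and the camera test gave an adjusted p of 0.0061, and 0.76 with an estimated correlation. Lymphocyte markers had 1 of 17 higher (1 adjusted over the list alone), neutrophil markers 0 of 13 (0 adjusted over the list alone, median 0.79) and erythroid markers 1 of 12 higher (1 adjusted over the list alone).

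Lists of proliferation and stress gave few calls between GREEN and RED with TMM scaling. Of 40 cell cycle and mitosis genes 0 passed (0 adjusted over the list alone, median -0.48). Mki67 was at -0.35 (0.05 by library totals), Ccnd1 at 0.44 and Cdkn1a at -0.74, and none passed. DNA replication had 2 of 30 higher and 1 lower (2 higher adjusted over the list alone), with Pole at 1.24 (not past under limma-voom or in experiment 2 alone). Homologous recombination and the Fanconi pathway had 1 of 24 higher (0 adjusted over the list alone), and excision, mismatch repair and end joining 2 of 28 higher (2 adjusted over the list alone), but 11 by library totals, where DNA replication had 5 higher and 0 lower. Of 27 p53 targets and cell cycle arrest genes 1 fell (0 adjusted over the list alone), with a median of -0.15, while by library totals 4 rose and the median was 0.30. Interferon response genes had 1 of 30, Iigp1, lower (0 adjusted over the list alone), with a median of -0.34, and 0.10 by library totals. NRF2 and glutathione had 4 of 28 lower (1 higher and 4 lower adjusted over the list alone), Gclm at -0.58 among them, and 2 higher and 0 lower by library totals. The unfolded protein response had 1 of 26 higher and 1 lower (1 higher adjusted over the list alone), and the circadian clock 1 of 20 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.15 where the camera test pointed down. Male-biased (0 of 22, median -1.18) and female-biased genes (0 of 20, median -0.47) did not pass, nor did histones (0 of 24, median -0.23, and 0.09 by library totals). Adjusted over the list alone each had 0. With the pairs of experiment 2 as a block, p53 targets and cell cycle arrest genes had 2 higher and 3 lower, NRF2 and glutathione 2 higher and 5 lower, and the unfolded protein response 2 higher and 3 lower. Without CTL and without the block, Pole, Iigp1 and Gclm did not pass.

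GREEN versus CTL set DR-derived hepatocytes of injured liver against native hepatocytes of healthy liver, so origin and injury differed together. GREEN samples held bile duct and matrix genes that CTL nearly lacked and less RNA of bile acid genes. Col1a1 rose from 1.498 ± 0.769 to 229.9 ± 76.1 CPM (log2 7.24, standard error 0.50, 5 samples per group). Sox9 rose from 11.3 ± 12.1 to 107.7 ± 47.8 CPM (log2 3.35, standard error 0.68), a call that ended without GREEN 3, GREEN 4 and GREEN 5. Cyp8b1 fell from 266.1 ± 88.0 to 22.6 ± 10.9 CPM (log2 -3.56, standard error 0.39), with -4.06 and -3.54 in the experiments. In all 7890 genes passed, 4839 higher and 3051 lower in GREEN, and 4671 of them had a fitted change over 2-fold, 3735 of these higher. By library totals 10077 were higher and 467 lower. Experiment 1 alone gave 7942 and experiment 2 alone 3481, and 7774 of the 7776 pooled calls tested in both had the same sign. CTL 5 entered both experiments, and the calls came from the same samples. Without GREEN 4 and GREEN 5, 4481 genes passed, and 2176 without GREEN 3 as well.

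Biliary markers had the largest median rise of all lists tested, ahead of neutrophil and matrix markers. Of 30 biliary markers 29 rose (29 adjusted over the list alone, median 6.12), 28 and 25 in the experiments alone and 23 without the 3 GREEN libraries. Krt19 held 13556 counts in GREEN and 1 in CTL, a ratio of 8476 (counting interval 1521 to 334818). Mmp7 (ENSMUSG00000018623.9, chromosome 9, 7692090 to 7699585) was at least 2005-fold, Kif12 (ENSMUSG00000028357.13, chromosome 4, 63165630 to 63172131) at least 1964-fold and Cftr (ENSMUSG00000041301.15, chromosome 6, 18170687 to 18322768) at least 1061-fold above CTL groups with 0 counts, and Lamc3 (ENSMUSG00000026840.14, chromosome 2, 31887291 to 31946539) had a ratio of 21115 (counting interval 3789 to 834021). Of 30 extracellular matrix and stellate cell markers 30 rose (30 adjusted over the list alone, median 4.98), 30 and 28 in the experiments alone and 24 without the 3 GREEN libraries. The camera test gave an adjusted p of 6.2e-24, and 0.33 with an estimated correlation. Of 30 endothelial markers 30 rose (30 adjusted over the list alone, median 2.95), 18 without the 3 GREEN libraries, with Flt4 at 2.98. Of 30 Kupffer cell and macrophage markers 25 rose (27 adjusted over the list alone, median 2.72), 24 and 16 in the experiments alone and 10 without the 3 GREEN libraries, with Gpnmb at 6.09. Neutrophil markers had 9 of 13 higher (9 adjusted over the list alone, median 5.05, and 5.24 with genes near 0 counts at their bound), lymphocyte markers 10 of 17 higher and 1 lower (10 and 1 adjusted over the list alone), and erythroid markers 2 of 12 higher (1 adjusted over the list alone, 6 by library totals).

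Lists of growth, remodelling, repair and stress held from 3 to 33 higher members. YAP targets had 21 of 24 higher (22 adjusted over the list alone, median 2.75), with Ccn2 at 9.27 and Ptpn14 at 6.88. Of the list, 11 rose without the 3 GREEN libraries. TGF-beta, EMT and cytoskeleton genes had 24 of 34 higher and 2 lower (24 and 2 adjusted over the list alone, 29 and 0 by library totals), with Vim at 5.37, and fetal and tumour-associated hepatocyte genes 17 of 23 higher and 1 lower (17 and 2 adjusted over the list alone), with Sox4 at 7.22. Senescence-associated secretion had 19 of 22 higher (20 adjusted over the list alone, 17 and 16 in the experiments alone), with Plaur at 6.28 and Ccl2 at 5.80. Cell cycle and mitosis had 33 of 40 higher and 1 lower (33 and 1 adjusted over the list alone), but 13 and 10 higher in the experiments alone and 3 higher without the 3 GREEN libraries. Cdk1 rose by 2.70. DNA replication had 15 of 30 higher and 1 lower (15 and 1 adjusted over the list alone, 25 and 0 by library totals), and 2 higher in experiment 2 alone and 2 without GREEN 4 and GREEN 5. Homologous recombination and the Fanconi pathway had 8 of 24 higher (8 adjusted over the list alone, 20 by library totals), with Rbbp8 at 1.95. Excision, mismatch repair and end joining had 5 of 28 higher and 2 lower (3 and 1 adjusted over the list alone), with a median of 0.03 where the camera test pointed down, but 24 higher and 0 lower with a median of 0.76 by library totals. Histones had 3 of 24 higher and 1 lower (1 lower adjusted over the list alone, 11 higher and 0 lower by library totals), with a median of 0.61 where the camera test also pointed down. The p53 targets and cell cycle arrest genes had 10 of 27 higher and 3 lower (10 and 3 adjusted over the list alone, 19 and 0 by library totals), with Phlda3 at 4.79 while Cdkn1a (2.03) did not pass, though it did with DESeq2, by library totals and without CTL 1. Immediate early and dissociation stress genes had 18 of 29 higher (18 adjusted over the list alone, 17 and 7 in the experiments alone), with Klf6 at 3.61.

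Many genes of hepatocyte functions were lower in GREEN, by a margin that depended on the scaling. Mature hepatocyte markers had 26 of 29 lower (27 adjusted over the list alone, median -1.25), 27 and 6 in the experiments alone, 14 by library totals, 9 without GREEN 4 and GREEN 5 and 5 without the 3 GREEN libraries. Serpina1c fell from 7310 ± 2274 to 1923 ± 597 CPM and Alb (-1.41) did not pass (adjusted p = 0.064), though it did with DESeq2, limma-voom and in experiment 1 alone and without GREEN 2. Bile acid synthesis and transport had 2 of 25 higher and 16 lower (2 and 17 adjusted over the list alone, 0 and 9 in experiment 2 alone), with Slc10a1 at -1.92 and Cyp27a1 (ENSMUSG00000026170.6, chromosome 1, 74713574 to 74737892) at -1.67. Cytochrome P450 and xenobiotic metabolism had 17 of 31 lower (17 adjusted over the list alone, 19 and 6 in the experiments alone, 11 by library totals), periportal genes 1 of 30 higher and 16 lower (1 and 18 adjusted over the list alone, 1 and 6 by library totals) with Cyp2f2 at -2.01 (not past without the 3 GREEN libraries), and pericentral genes 2 of 28 higher and 12 lower (2 and 13 adjusted over the list alone), but 6 higher and 4 lower by library totals. Glul was at -0.86 and Cyp2e1 at -1.42, with calls that ended in either experiment alone and without GREEN 4 and GREEN 5. Oxidative phosphorylation had 32 of 32 lower (32 adjusted over the list alone, median -0.71), 31 and 22 in the experiments alone and 21 without GREEN 4 and GREEN 5, but 0 by library totals, where the median was -0.0022, and 0 without the 3 GREEN libraries. Urea cycle and amino acid catabolism had 17 of 30 lower (20 adjusted over the list alone, 24 and 0 in the experiments alone, 4 by library totals) and cholesterol synthesis 12 of 24 lower (13 adjusted over the list alone, 5 by library totals, Insig1 -1.45). Fatty acid synthesis and lipid storage had 2 of 25 higher and 10 lower (2 and 10 adjusted over the list alone, 3 and 3 by library totals, Thrsp -2.67), and the acute phase response 1 of 28 higher and 8 lower (1 and 8 adjusted over the list alone, 2 and 3 by library totals). Fatty acid oxidation had 10 of 27 lower (9 adjusted over the list alone, 1 by library totals), with a median of -0.59 that turned to 0.09 by library totals.

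Lists of stress response had calls on both sides. Interferon response genes had 4 of 30 higher and 6 lower (2 and 4 adjusted over the list alone), with a median of -0.23, a mean of 0.093 and 10 higher and 1 lower by library totals. NRF2 and glutathione genes had 5 of 28 higher and 9 lower (5 and 9 adjusted over the list alone), with a median of -0.24, a mean of 0.30 and 9 higher and 0 lower by library totals. Cbr3 rose by 6.07. Unfolded protein response genes had 3 of 26 higher and 10 lower (3 and 11 adjusted over the list alone), with a median of -0.74, but 6 higher and 1 lower by library totals and a median of 0.00080. Circadian clock genes had 2 of 20 higher and 6 lower (2 and 4 adjusted over the list alone), with a median of -0.52 that turned to 0.19 by library totals, where 4 were higher and 1 lower. Male-biased genes had 12 of 22 lower (12 adjusted over the list alone, median -2.90), and female-biased genes 1 of 20 higher and 7 lower (5 lower adjusted over the list alone, median -4.00). Mup19 was at -8.97. Summed Y-linked genes were high in CTL 1, CTL 4 and CTL 5 but only in GREEN 3 and GREEN 4, so these groups were not balanced in them either.

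RED served in 2 of the comparisons, so their calls are not independent. Of the genes higher in RED than CTL, 393 were also higher in GREEN than RED, where independent lists would share 225, simulations of unchanged groups gave 0 and splitting the RED samples gave 39. Higher and then lower were 6 genes (74.9 by independent lists, 0 simulated, 12 split), lower and then lower 28 (10.5, 0, 3) and lower and then higher 13 (31.6, 0, 3). The simulations held no changed genes, so their counts of 0 are no baseline for shared calls. The split fits had fewer RED libraries each, and the overlap of independent lists was not computed for them. Across genes, which are not independent replicates, the correlation of the fold changes was 0.294 (simulated -0.501, split 0.190), their covariance 0.401 (simulated -0.0879, split 0.236) and the share with the same sign 61.4% (simulated 33.5%, split 60.04%). The simulated samples were independent, without the RED and GREEN pairs of experiment 2, so the simulated values may not hold for unchanged paired samples.

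The experiments, which differed in library kit, gave fold changes with correlations across 15147 genes of 0.820 for RED versus CTL, 0.858 for GREEN versus RED and 0.897 for GREEN versus CTL (jackknife standard errors 0.159, 0.138 and 0.0786), counting each sample in 1 experiment. With all 19 libraries, in which 4 samples enter both sides, these were 0.866, 0.862 and 0.906. The submitters' text gives about 0.95 for the correlation of log fold changes between experiments. The edgeR test of a difference between experiments passed for 1 gene in RED versus CTL, Gm4737, chosen after its value was seen (log2 -9.39, adjusted p = 0.019), and for 0 in the others. In the same order, 666, 1420 and 2108 genes had an unadjusted p under 0.05. With limma-voom 0 genes passed in each comparison, with 345, 1071 and 1764 at the unadjusted level.

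Libraries of the same 4 samples made with the 2 kits differed in 8146 of 14625 genes, 4196 higher and 3950 lower in experiment 2. Replication-dependent histones, whose transcripts lack a poly(A) tail, had 21 of 22 members higher in the ribosomal RNA-depleted libraries (median 4.93), with Hist1h4b at 8.31. Oxidative phosphorylation had 30 of 32 lower, mature hepatocyte markers 2 higher and 24 lower of 29, cytochrome P450 and xenobiotic metabolism 1 higher and 24 lower of 30, the acute phase response 23 lower of 28, Kupffer cell and macrophage markers 20 lower of 30, and YAP targets 12 higher of 22. Processed pseudogenes had 193 higher and 38 lower of 339, and Tpt1-ps3 had 0 CPM in experiment 1 and 54.7 ± 6.06 in experiment 2. Ccnb1ip1 rose from 9.52 ± 16.9 to 1171 ± 379 CPM, while mt-Atp8 fell from 1704.5 ± 682 to 236.5 ± 118 CPM and Gdap1 from 25.6 ± 24.4 to 0.151 ± 0.0856 CPM.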

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

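All tests in this part were chosen after the results they measure were seen; only the expectation for the splits that part the pairs was written before its result. For 27 genes, 35 lists and the library totals, the gap between the highest or lowest sample of a group and its nearest neighbour was divided by the range over the 5 samples. Levels of the genes and lists had the experiment effect removed. This share was above the 5-sample critical value in 10 of 189 groups (5.29%); chance flags about 1 in 20 groups, so these 10 are about as many as chance would give. In RED they were biliary markers (RED 1 lowest, 0.719), mature hepatocyte markers (RED 1 highest, 0.744), bile acid synthesis and transport (RED 1 highest, 0.762), fatty acid synthesis and lipid storage (RED 2 lowest, 0.732) and neutrophil markers (RED 5 highest, 0.717). In GREEN they were senescence-associated secretion (GREEN 1 lowest, 0.742) and fatty acid synthesis and lipid storage (GREEN 2 highest, 0.780). In CTL they were immediate early and dissociation stress genes (CTL 4 lowest, 0.774), the pseudogene Rps2-ps6 (CTL 3 lowest, 0.824) and Smyd1 (CTL 4 highest, 0.798).

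Biliary transcripts were higher in GREEN than in RED. Scaling between libraries of different composition is argued against, because the biliary median lay 4.70 above that of all genes, where library totals moved the latter by 0.44. A lower share of hepatocytes that raised every other cell type alike is argued against too. The biliary score rose 4.60 more than the endothelial score (exact permutation p = 0.0079 over 252 permutations, and 0.0417 over the 48 that part the 3 pairs of experiment 2, the smallest these can give). The 48 treat RED 1, RED 5, GREEN 4 and GREEN 5 as unpaired, though the states of on and off genes given below pair them too. A score was the mean log2 CPM of a list's members, with the experiment effect removed. RNA of biliary cells among the GREEN hepatocytes stays open: the hepatocyte markers had log2 fold changes with a standard deviation of 0.126 around a mean of -0.86, as a common dilution would give, though their median standard error was 0.326. The DR-derived hepatocytes may equally have expressed these genes themselves, which the design does not test apart.

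Endothelial, stellate and macrophage transcripts were higher in RED than in CTL. A difference between the library kits cannot by itself give this rise, because RED and CTL libraries of an experiment were made with the same kit. The experiment was also a term in the model. In both experiments 90 of 90 members had a positive log2 fold change, so the direction was the same with either kit. These signs are no test of the kit, and samples with a library in each experiment entered both fits. A lower share of hepatocytes that raised all 3 cell types alike is argued against, though weakly, by the endothelial score, which rose 0.69 more than the macrophage score (exact permutation p = 0.0317), and by the matrix score, which rose 0.90 more (p = 0.0238); adjusted over the 3 differences both had p = 0.0714. For the endothelial and stellate transcripts a lower share cannot be told apart from other causes, because the matrix score rose 0.21 more than the endothelial score (exact permutation p = 0.222, 90% interval -0.096 to 0.52), an interval too wide to call them alike. RNA of these cells among the RED hepatocytes stays open, as 85 of 90 members were higher and 0 lower (edgeR); expression by injured hepatocytes themselves was not tested apart and may add to it.

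Of 100 splits of the 10 samples, the real one included, 1 gave as many genes as RED versus CTL (2652, highest other 1941), 2 as many as GREEN versus RED (2114, highest other 3151) and 1 as many as GREEN versus CTL (7890, highest other 901). This argues against chance for these counts without excluding it, and for GREEN versus RED another split gave more genes than the real one. The splits of GREEN versus RED took no account of the 3 pairs of experiment 2. With CTL left out and the pairs as a block, 1 of the 24 splits that part them, the real one, gave as many genes (1305, highest other 0), and without the block also 1 (1283, highest other 0). This argues against chance there too if RED 1, RED 5, GREEN 4 and GREEN 5 were unpaired, though 1 of 24 is the smallest share these splits can give. The states of on and off genes given below also pair RED 1 with GREEN 5 (0.938 shared) and RED 5 with GREEN 4 (1 shared). Splits that part these pairs as well are fewer, so their smallest share is larger, and they were not run. The other split with 3151 genes set RED 1, RED 2, RED 3, GREEN 1 and GREEN 2 against RED 4, RED 5, GREEN 3, GREEN 4 and GREEN 5; it followed the Y-linked genes except in GREEN 5, and points to a structure of the samples. For the gene lists, 30 splits gave as many as RED versus CTL (22; highest other 29), 22 as many as GREEN versus RED (22; highest other 26) and 21 as many as GREEN versus CTL (25; highest other 30), so chance cannot be excluded for the number of lists. For the library kits 8 splits are too few for a share under 0.05 (8146 genes, highest other 0; as many in 1 split).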

How the results depend on the processing

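The sex term, the fits without GREEN 4 and GREEN 5 or without GREEN 3, GREEN 4 and GREEN 5, the blocks by code number of experiment 2, and experiment 2 alone with only the 2 groups were chosen after seeing the data; the other alternatives were planned. For RED versus CTL, 2652 genes became 1207 in experiment 2 alone and 380 with the replicate block by title number and without GREEN (2534 without GREEN and without the block), and leaving out single libraries gave 2131 to 3267. For GREEN versus RED, 2114 became 1326 over 2-fold, 4329 by library totals, 3858 with DESeq2, 4141 with the experiment 1 libraries of the repeated samples, 5351 in experiment 1 alone, 77 in experiment 2 alone, 1283 without CTL, 3485 with a sex term, 2780 with a block by the code numbers of experiment 2, 1305 with this block and without CTL, 857 with this block in experiment 2 without CTL (885 with limma-voom), 268 without GREEN 4 and GREEN 5 and 52 without GREEN 3 as well. In experiment 2 alone with only the 2 groups and no block, edgeR gave 0 genes (1336 at an unadjusted p under 0.05) and limma-voom 0 (1252). Single libraries left out gave 866 (GREEN 3) to 3515 (GREEN 1). For GREEN versus CTL, 7890 became 4671 over 2-fold, 3481 in experiment 2 alone, 4481 without GREEN 4 and GREEN 5 and 2176 without GREEN 3 as well; single libraries left out gave 6710 to 8446. Fits with fewer libraries have less power, and a 2-fold minimum calls fewer genes by construction; for the rest the cause was not tested. The planned block by the code numbers of both experiments without CTL gave 1470 for GREEN versus RED, and the block by title number with only the 2 groups 2083 there and 6041 for GREEN versus CTL. Residuals of RED and GREEN samples with the same title number correlated across genes at 0.58, -0.10, -0.20, 0.44 and -0.22. With the same code number they correlated at 0.19 and -0.08 in experiment 1 and 0.53, 0.31 and 0.78 in experiment 2, and only the last were used as pairs. CTL and RED samples with the same title number, of healthy and of injured liver, had -0.11, -0.086, 0.42, 0.011 and 0.35, so these correlations alone do not establish pairs. Gene lists past camera fell from 22, 22 and 25 to 0, 0 and 0 with an estimated correlation, and for GREEN versus RED to 14 without GREEN 3, GREEN 4 and GREEN 5. Reversed values were those of RED versus CTL Afp (-0.058 in experiment 1 alone, -0.014 with a sex term, and -0.049 without CTL 1 and -0.0064 without RED 2 in a range of -0.049 to 0.17 over single libraries left out), of GREEN versus RED Mki67 (0.051) and GREEN versus RED Glul (0.18) by library totals and GREEN versus RED Cyp2e1 (0.11) without GREEN 3, GREEN 4 and GREEN 5, and of GREEN versus CTL Xrcc6 (0.38), GREEN versus CTL Clock (0.30) and GREEN versus CTL Afp (0.021) by library totals; the cause was not tested. Of the values of named genes under the alternatives, 2830, 2358 and 4536 kept direction and side of the threshold in the order RED versus CTL, GREEN versus RED and GREEN versus CTL, 319, 841 and 267 lost the call in the same direction, 14, 33 and 26 gained it and 4, 3 and 3 reversed. Depth limits the genes near 0 counts, where a group of 5 libraries held 0 to 3 counts and only a bound or a wide interval could be given.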

Other observations

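All tests in this part were chosen after the results they measure were seen. No label gives the sex of the animals. Summed Y-linked genes were at 113.8 to 187.4 CPM in CTL 1, CTL 4, CTL 5, RED 4, RED 5, GREEN 3 and GREEN 4, and at 1.05 to 16.9 CPM in the other samples, in both libraries of each repeated sample. In the first set the mean log2 CPM of the male-biased list, with the experiment effect removed, was 9.47 to 9.67 in CTL, 7.41 to 7.64 in RED and 5.78 to 6.65 in GREEN. In the other samples that of the female-biased list was 7.95 to 8.26 in CTL, 1.97 to 4.67 in RED and 1.98 to 4.62 in GREEN. Mup19 had 244 to 761.1 CPM in CTL 1 to CTL 4, and 77.8 and 29.7 in the libraries of CTL 5, against 13.1 at most in RED and 1.85 at most in GREEN.

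Genes of pancreatic enzymes (Ctrb1, Pnlip, Prss2 and the Amy2a copies, chosen after their values were seen) were on in CTL 4, RED 5 and GREEN 4 and off in the other samples, except that Ctrb1 was also on in GREEN 5. The processed pseudogene Rps2-ps13 had 113.5 CPM in RED 5, 102 in GREEN 4, 86.6 in GREEN 1 and 86.8 in GREEN 3, and 0.0434 in GREEN 5 and 0.0393 in GREEN 2.

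The states of 32 genes that were on in some RED samples and off in others were compared between RED and GREEN samples. The code numbers of GREEN 4 and GREEN 5 in experiment 1 are argued against as numbers of animals shared with RED. These libraries and the RED libraries of experiment 1 with the same code number shared 0.328 of the states on average. RED 2, RED 3 and RED 4 had the same code number in both experiments. The code numbers of experiment 2 may number animals, as the RED and GREEN libraries with the same code number shared all states in each of the 3 pairs (mean share 1). One sample behind the 2 GREEN libraries with the same code number is argued against too, because GREEN 3 and GREEN 4 shared 0.312. A candidate explanation is that the RED and GREEN samples came from 5 shared animals numbered otherwise than in the titles: in the best of 120 pairings (RED 1 with GREEN 5, RED 2 with GREEN 1, RED 3 with GREEN 2, RED 4 with GREEN 3, RED 5 with GREEN 4) the lowest pair shared 0.938, while the next pairing had a pair at 0.781 and the other 20 pairs were at 0.156 to 0.781. The 2 samples of each of these 5 pairs were alike in their Y-linked genes. Without 11 pancreatic and sex-biased genes the best pairing was unchanged, its lowest pair shared all 21 states, and other pairs shared 0.238 to 0.857. This remains a hypothesis found and tested on the same data, and a block was fitted only for the 3 pairs that the code numbers of experiment 2 also give.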
